A study of Mus musculus with 6 samples.

How the data were processed

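Gene expression was measured by RNA sequencing in 6 libraries of sorted cells from the embryonic cortex of C57BL/6J mice. Embryos carried a GFP reporter for Tbr2 (Eomes), a transcription factor of intermediate progenitors, and an mRFP reporter for doublecortin (DCX), a microtubule protein of young neurons. Per the labels' protocols, cells positive for both colors were collected by fluorescence-activated cell sorting as intermediate progenitor cell-derived neurons (IPN), and cells with red fluorescence alone as non-IPN. Each population gave 1 library at embryonic days 13.5, 15.5 and 16.5. The E15.5 libraries came from 1000000 cells per population without amplification. The E13.5 and E16.5 libraries came from 10000 cells per population, and their transcriptome was amplified before library preparation, per the labels' protocols. Amplification and cell number therefore changed together with age, and no difference in level between E15.5 and another age was tested. The population by day term and later comparisons of population ratios did set the E15.5 pair beside the amplified pairs.

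Per the submitters' processing notes, CASAVA 1.9, TopHat 1.2.0, SAMtools 0.1.18 and edgeR were used with the mouse build mm9. The roles of these tools, the read counter, the gene annotation and the scaling method are not given in the sources used here. Each deposited file paired gene symbols with whole numbers, and these deposited values were treated as a signal scaled from read counts and not as raw counts. The upper quartile over genes was 1502 and 1501 in the E15.5 pair and 438 to 444 in the 4 amplified libraries, although column totals differed. In IPN at E13.5, 151 genes had a value that multiplication of whole counts by 1.0654 cannot reach, against 453.0 expected from neighboring values. In non-IPN at E13.5 there were 162 such genes for a multiplier of 1.0588, against 495.5 expected. In IPN at E16.5, 1216 genes had a value reached from more than 1 count for a multiplier of 0.924, against 832.0 expected. The other 3 libraries showed no clear pattern. The planned count models had assumed raw counts, and were replaced by the test planned for normalized values.

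The 6 files were joined by symbol, since row order differed between them. Of 20373 rows, 6 rows of 3 symbols listed 2 times (Cngb1, Gm5506 and Tff1) were dropped, which left 20367 genes, of which 19561 were above 0 in at least 1 library and were tested. A further 25 symbols had been turned into dates and were kept under those names. Column totals ran from 12583677 to 32538995. Because the values were scaled, the true depth is unknown and no counting interval was computed. Levels are given as CPM, the deposited value per 1000000 of its column total. No genome of the authors' build was used, and no coordinates are given.

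Differences were tested with limma 3.58.1 in R 4.3.3 (trend and robust options) on log2(value + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05, so that fold changes of low genes are understated. The first model had population and age as factors, with 2 residual degrees of freedom, and gave the IPN minus non-IPN difference and the E16.5 minus E13.5 difference. A second model added population by embryonic day as a number, with 1 residual degree of freedom. Age served as the pairing of the libraries, since both populations of an age were sorted from the same cortices, per the labels' protocols. The ages were the only replication of the population difference, so the residual of a gene is how its difference varied across ages. Limma moderated that spread toward the spread of other genes, with a median prior of 8.3 degrees of freedom beside the 2 residual ones. In the second model the median prior was 14.5 beside 1. A call therefore does not by itself show that the difference of a gene was steady across ages. The p-values of the age difference use the same residual, the spread of the population difference over all 3 ages, E15.5 included. The labels name no separate animals for any library. No 2 libraries held the same values, and correlations of log2 values between libraries ran from 0.812 to 0.959.

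Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, for 30 of 32 lists with at least 3 measured genes. Of the 448 list members, 433 were found by symbol or a given alias, 1 by an older symbol in the reference table, and 14 were not analysed here, among them Xist and the genes of the mitochondrial genome. The design planned log2 CPM for these tests, and log2(value + 1) was used instead. Tests, lists and the rule for named genes were fixed before the data were examined. The rule took Eomes and Dcx, the 10 largest changes per direction between populations and the 8 largest per direction between ages among called genes with at least 16 CPM and the same sign in every pair, and up to 5 per direction for the population by day term. From each list it took up to 4 called genes (6 in the projection neuron, intermediate progenitor and GABA lists) and up to 2 not called, by mean level. Some genes that the rule took are not reported here.

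The fits were tested on simulated values with the fitted means of the real genes and the spread of each gene as moderated by limma. They held 50 changed genes at each of 4 sizes and 5 planted lists of further changed genes. For the population comparison (19395 genes), 17 of 50 genes were recovered at a log2 change of 1, 41 of 50 at 2, and 49 of 50 at 3 and again at 4, while 24 of 19120 unchanged genes were called. For the age comparison (19328 genes), 13, 36, 44 and 49 of 50 were recovered at the same sizes. For the population by day term (19446 genes), 4, 32, 47 and 49 of 50 were recovered at slopes of 0.5, 1, 1.5 and 2. The preset camera test called 5 of 5 planted lists in each comparison, and with an estimated correlation it called 0 of 5 in each. The preset test also called 2 of 25 unchanged lists in the age simulation and 0 of 25 in the others. The simulated noise was normal, independent between genes and of the same spread in each library, so the count of unchanged genes called holds only for such noise. The test with an estimated correlation called 0 of 5 planted lists even without correlated noise. Not passing it therefore does not show that correlation between members undid a list. In the real population comparison, estimated correlations within lists reached 0.59 for radial glia genes and 0.973 for red blood cell genes. The simulation therefore does not test the preset correlation on lists with correlated members.

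Alternatives were 3 other scalings, pseudocounts of 0.1 and 5, minimum levels, fits without the age term and fits without single ages or libraries. Transcript length was taken from GENCODE M21 on GRCm38, the longest protein-coding transcript per symbol, for 9246 of 9349 genes with a mean of 10 CPM (98.9%), and its trend was removed per library with a lowess of span 0.3. Python 3.11.15 with pandas 2.3.3 joined the files and matplotlib 3.10.9 drew the figures.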

Results

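The data set compared neurons sorted as derived from intermediate progenitors (IPN) with the remaining DCX-positive neurons (non-IPN) of the embryonic mouse cortex, which the series title frames as projection neurons and interneurons. There were 3 libraries per population, 1 each at E13.5, E15.5 and E16.5. Column totals were 15472487 for IPN and 13986155 for non-IPN at E13.5, 32538995 and 31364256 at E15.5, and 14620980 and 12583677 at E16.5. Between 7657 and 9694 genes per library reached 10 CPM (the deposited value per 1000000 of the column total). Errors of fitted log2 fold changes are standard errors from 1 fit of all 6 libraries, in which both comparisons share 1 residual spread per gene.

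The reporter genes of the sort were examined first. Eomes was at 437.12 CPM in IPN and 214.24 in non-IPN at E13.5, at 101.71 and 72.50 at E15.5, and at 98.42 and 72.00 at E16.5. Its log2 ratio was positive at all 3 ages, but the fitted difference of 0.79 ± 0.22 did not pass the test (limma, adjusted p = 0.101). Dcx, present in both gates, had a fitted difference of -0.01 ± 0.26 (adjusted p = 1). Its log2 ratio was 0.85 at E13.5, -0.64 at E15.5 and -0.23 at E16.5.

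**Figure D1:**
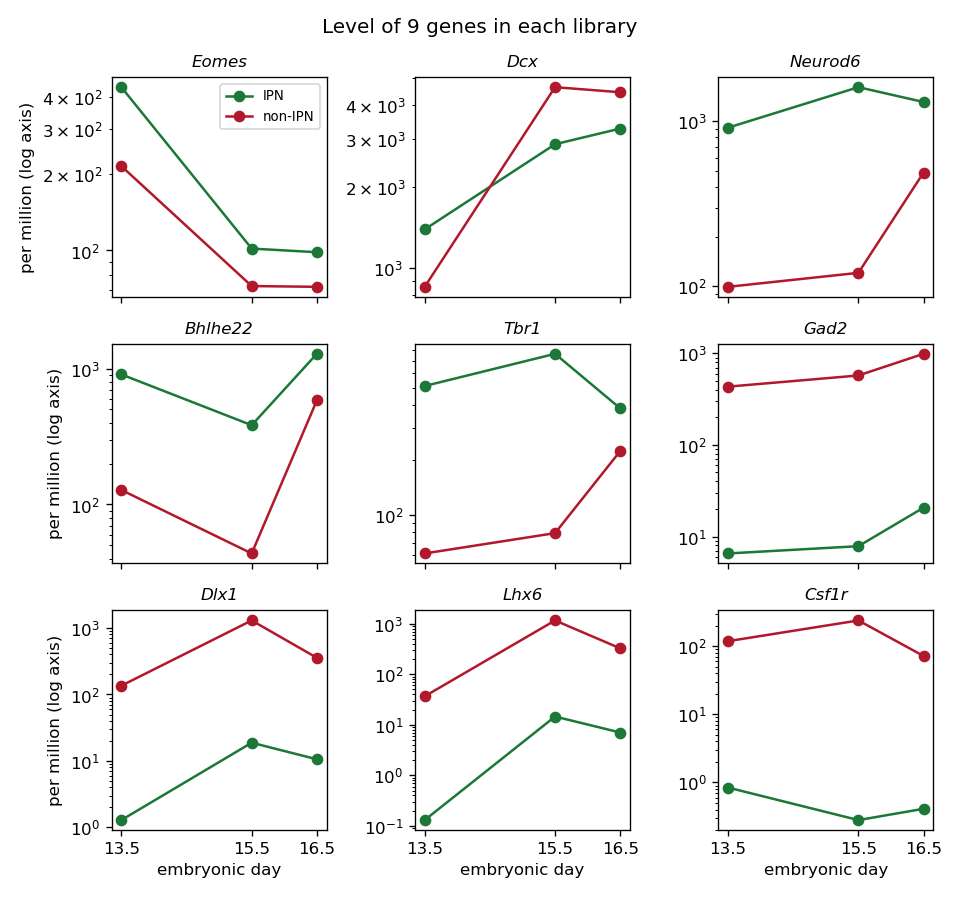
Level of 9 genes in CPM (log axis) against embryonic day, with 1 point per library, IPN in green and non-IPN in red. Neurod6, Bhlhe22 and Tbr1 lie higher in IPN and Gad2, Dlx1, Lhx6 and Csf1r lie higher in non-IPN at each age.

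Genes of glutamatergic projection neurons were higher in IPN. Of 18 members of that list, 12 were called higher and 0 lower (15 higher when adjusted over the list alone). They included the transcription factors Zfp238 (log2 fold change 2.47 ± 0.29), Nfib (2.01 ± 0.26), Neurod6 (2.93 ± 0.35), Bhlhe22 (2.50 ± 0.32) and Tbr1 (2.51 ± 0.40). Mef2c was not called (-0.34 ± 0.21, adjusted p = 0.554). The list passed camera at adjusted p = 1.68e-11 and not with an estimated correlation (adjusted p = 0.375). The latter test called 0 of 5 planted lists in each simulation, so not passing it, here and below, is weak evidence against a list. The median log2 ratio of the projection neuron list was 2.82 at E13.5, 3.07 at E15.5 and 0.99 at E16.5.

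Layer genes and genes of newborn neurons were in part higher. Of 15 deep-layer genes, 4 were higher (11 adjusted over the list alone), among them Sox5 (2.41 ± 0.47) and Pcp4, a calmodulin-binding protein (2.24 ± 0.40), while Bcl11b was not called (1.07 ± 0.32, adjusted p = 0.123). Of 15 upper-layer genes, 4 were higher, including Plxna4 (1.77 ± 0.31) and Unc5d (2.23 ± 0.40), and Cux2 was lower (-2.19 ± 0.31); adjusted over the list alone, 9 were higher and 2 lower. Of 16 genes of intermediate progenitors and newborn neurons, Insm1 (1.19 ± 0.24), Neurod1 (2.86 ± 0.25) and Nhlh1 (2.82 ± 0.52) were higher, and adjusted over the list alone 6 were higher and 1 lower. Neurog2, a proneural factor, was not called (-0.14 ± 0.22, adjusted p = 0.830). These lists passed camera (adjusted p = 1.35e-07, 0.00117 and 0.00347), and none did with an estimated correlation (adjusted p = 0.402, 0.492 and 0.375). Without the E15.5 pair the list of intermediate progenitors and newborn neurons was at adjusted p = 0.05 and no longer passed.

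Axon guidance and neuronal genes were in part higher in IPN. Of 24 guidance receptors and adhesion genes, 9 were higher (12 adjusted over the list alone, with 2 lower), among them Cntn2 (2.48 ± 0.32), the netrin receptor Dcc (1.70 ± 0.33) and the Slit receptor Robo2 (1.10 ± 0.20). Of 20 pan-neuronal genes, Gap43 (1.70 ± 0.26), Nefm (1.95 ± 0.38) and Uchl1 (1.25 ± 0.27) were higher, and adjusted over the list alone 6 were higher and 2 lower. Both lists passed camera (adjusted p = 5.56e-08 and 0.00117) and neither did with an estimated correlation (adjusted p = 0.375 and 0.513). The pan-neuronal median log2 ratio was 1.34 at E13.5, 0.16 at E15.5 and 0.13 at E16.5, and without the E13.5 pair the list no longer passed camera (adjusted p = 0.224).

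Most GABA and Dlx genes were lower in IPN. Of 14 genes of GABA synthesis and the Dlx family, 11 were lower (13 adjusted over the list alone), with a median log2 fold change of -5.50. Gad2 and Gad1, the enzymes that make GABA, differed by -5.80 ± 0.24 and -5.82 ± 0.40. The transcription factors Dlx1 (-5.80 ± 0.33) and Dlx2 (-6.81 ± 0.55) were also lower. The list passed camera (adjusted p = 2.85e-17), but not with an estimated correlation (adjusted p = 0.375).

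Of 14 genes of interneurons from the medial ganglionic eminence, 9 were lower (12 adjusted over the list alone), including Lhx6 (-6.33 ± 0.40) and Maf (-5.66 ± 0.35). Maf is also known from macrophages, whose genes moved the same way. Of 11 genes of the caudal ganglionic eminence, Sp8 (-5.21 ± 0.71) and Npas3 (-3.60 ± 0.46) were among 3 lower, the cannabinoid receptor Cnr1 was higher (1.78 ± 0.34) and Nr2f2 was not called (-0.30 ± 0.30, adjusted p = 0.75); 1 was higher and 6 lower adjusted over the list alone. Of 13 subtype peptides and calcium-binding proteins, 5 were lower, also adjusted over the list alone, with Sst at -6.71 ± 0.42, Npy at -3.95 ± 0.53, Calb1 at -7.92 ± 0.91 and Nxph1 at -5.46 ± 0.43. Reln was not called (-0.20 ± 0.37, adjusted p = 0.847). The 3 lists passed camera (adjusted p = 1.03e-11, 0.0303 and 0.000118) and not with an estimated correlation (adjusted p = 0.375, 0.513 and 0.375). The median log2 ratio of the caudal list was 0.27 at E13.5, -4.19 at E15.5 and -1.42 at E16.5, so it was not lower in IPN at E13.5. The caudal list no longer passed camera without the E15.5 pair (adjusted p = 0.246) or without the E16.5 pair (adjusted p = 0.256).

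Receptors and migration genes went both ways. Of 17 glutamate receptor genes, the AMPA receptor subunit Gria2 was among 2 higher (1.05 ± 0.23), and Gria1 (-2.95 ± 0.27), Gria4 (-2.85 ± 0.27) and Grm5 (-2.22 ± 0.30) were among 4 lower. Of 16 GABA receptor and chloride transporter genes, the chloride exporter Slc12a5 alone was called (-2.28 ± 0.44). Of 20 synaptic genes, Sv2b was higher (3.51 ± 0.54) and Nrxn3 lower (-6.38 ± 0.30). Of 14 migration genes, Robo1 (1.57 ± 0.23), Nrp1 (1.79 ± 0.24) and Kit (1.82 ± 0.27) were higher and Erbb4 (-4.82 ± 0.66) was among 2 lower, while Cxcr7 was not called (-3.58 ± 0.93, adjusted p = 0.204). Adjusted over the list alone, 2 higher and 6 lower were called among glutamate receptors, 0 and 1 among GABA receptors, 5 and 2 among synaptic genes and 5 and 3 among migration genes. None of these 4 lists passed camera (adjusted p = 0.154, 0.659, 0.0616 and 0.375), but the glutamate receptor list passed as lower without the E13.5 pair (adjusted p = 0.00485) and the synaptic list as higher without the E16.5 pair (adjusted p = 0.0282).

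Genes of microglia and macrophages, which are not neurons, were lower in IPN for all 12 list members (12 adjusted over the list alone), with a median log2 fold change of -7.63 (camera adjusted p = 1.94e-19; adjusted p = 0.375 with an estimated correlation). The summed level of the list was 5.3, 2.3 and 2.9 CPM in IPN and 973.3, 967.7 and 503.0 in non-IPN at E13.5, E15.5 and E16.5. The receptors P2ry12 (-8.87 ± 0.54), Csf1r (-7.81 ± 0.61) and Cx3cr1 (-8.06 ± 0.57) and the complement gene C1qb (-7.12 ± 0.58) were among them. Of the 10 largest decreases picked by the rule, Tyrobp (-8.07 ± 0.67) and Fcer1g (-8.08 ± 0.73) were also on the microglia and macrophage list. Sepp1 (-8.94 ± 0.64), Emr1 (-8.79 ± 0.69), Ctss (-8.64 ± 0.75) and P2ry13 (-7.80 ± 0.87) were on none of the lists, which assigns them to no cell type. Calb1 was on the list of interneuron peptides and calcium-binding proteins. Emr1, Ctss and Fcer1g were listed at 0 in IPN at E16.5, P2ry13 at E15.5 and Calb1 at E13.5 and E16.5. Sepp1 was at 0.07 CPM in IPN at E16.5 and Tyrobp at 0.03 in IPN at E15.5. The sizes of all these changes depend on the pseudocount.

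Progenitor and cell cycle genes were in part lower in IPN. Of 29 cell cycle genes, Mki67 (-1.32 ± 0.23), Mcm6 (-1.28 ± 0.29) and Mcm3 (-1.85 ± 0.42) were lower (9 adjusted over the list alone). The median log2 ratio of that list was -1.40 at E13.5, -1.06 at E15.5 and only -0.07 at E16.5. Of 21 radial glia genes, Sox2 alone was called (-3.64 ± 0.29; 9 adjusted over the list alone), and Vim and Fabp7 were not (-0.55 ± 0.26 and -0.91 ± 0.32). Both lists passed camera (adjusted p = 3.65e-09 and 5.59e-06) and neither did with an estimated correlation (adjusted p = 0.513 for each). The radial glia list summed to 7083.2 CPM in non-IPN and 1786.5 in IPN at E13.5, 1058.7 and 1289.5 at E15.5, and 1962.0 and 1718.8 at E16.5. It no longer passed camera without the E13.5 pair (adjusted p = 0.0534).

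Blood genes separated the populations at E13.5. Hemoglobin genes took 5.02% of the total of the E13.5 non-IPN library and at most 0.0302% of any other. The red blood cell list had a median log2 ratio of -12.76 at E13.5, -1.38 at E15.5 and 0.74 at E16.5, with 1 of 11 genes called, Hba-x (-6.50 ± 1.42), also adjusted over the list alone. It passed camera (adjusted p = 0.0021), not with an estimated correlation (adjusted p = 0.567), and not without the E13.5 pair (adjusted p = 0.379). Hemoglobin genes share reads with near-identical copies, so their single values are uncertain. In non-IPN at E13.5, Hba-a1 was at 11749.16 CPM and Hba-a2 at 11756.89, so the 5.02% may hold the same reads more than 1 time. Hba-x was listed at 0 in IPN at E16.5.

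The remaining lists did not pass camera. In the striatal list of 15 genes, Tac1 (-4.81 ± 0.89) and Ikzf1 (-6.45 ± 0.80) were lower and Ppp1r1b higher (3.41 ± 0.74); Ikzf1 is also known from blood and microglial cells, and Tac1 was listed at 0 in IPN at E15.5 and E16.5. In the Notch list of 16, Hey1 was higher (1.48 ± 0.27), and in the astrocyte list of 8, Apoe, which macrophages also express, was lower (-5.35 ± 0.50). No member was called among Cajal-Retzius genes, subplate genes, early temporal progenitor genes, oligodendrocyte precursor genes, endothelial and pericyte genes, meningeal genes, choroid plexus genes, immediate early genes or the 4 sex-linked genes. Adjusted over the list alone, 1 higher and 2 lower were called in the striatal list, 2 and 7 in the Notch list, 1 and 2 in the astrocyte list, 1 and 3 among subplate genes and 0 and 1 among early progenitor genes. The sex-linked list passed as lower without the E13.5 pair (adjusted p = 0.0303).

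The largest increases in IPN picked by the rule were the melanocortin receptor Mc4r (3.68 ± 0.58), Sv2b, Lrrtm3 (3.16 ± 0.65), the potassium channel Kcna1 (2.95 ± 0.53), Neurod6, Abcc8 (2.93 ± 0.60), Hs3st4 (2.93 ± 0.48), Neurod1, Nptx1 (2.81 ± 0.37) and the ryanodine receptor Ryr3 (2.72 ± 0.49). Over all 19561 genes, limma called 664 (3.39%), with 192 higher and 472 lower in IPN. Each of the 664 had the same sign at all 3 ages. The test itself favors this, since it sets the mean difference against its spread across those ages. Of 30 lists, 14 passed camera at the preset correlation, 6 higher and 8 lower, 0 passed with an estimated correlation and 6 passed fry. Those 6 were the GABA and Dlx, peptide and microglia lists (fry adjusted p = 0.0208 each), the list of intermediate progenitors and newborn neurons (0.0325), and the medial and astrocyte lists (0.0474 each), of which the astrocyte list did not pass camera. Without the E15.5 pair, the only one not amplified, 54 genes were called (1 higher, 53 lower), and 48 of the 70 called genes followed here no longer passed. Among genes with a mean of 10 CPM, 358 were called, 155 higher and 203 lower. Without the age term, limma called 0 genes (676 at an unadjusted p under 0.05), or 30 and 35 with column totals and median-of-ratios scaling.

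**Figure D2:**
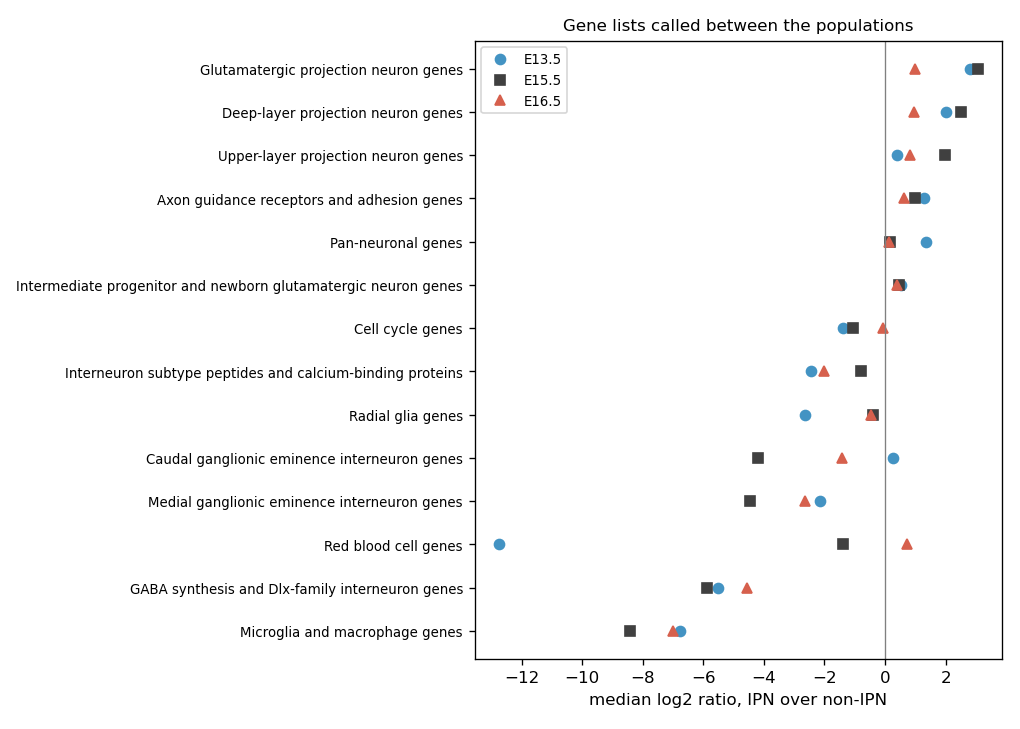
Median log2 ratio of IPN over non-IPN for the 14 gene lists that passed camera, with 1 point per age (circles E13.5, squares E15.5, triangles E16.5). The microglia list lies at -6.76, -8.41 and -7.01, and the red blood cell list reaches -12.76 at E13.5 alone.

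Between E13.5 and E16.5, most cell cycle genes and part of the progenitor and newborn neuron genes fell. Of 29 cell cycle genes, 22 fell (28 adjusted over the list alone), among them Mki67 (-2.11 ± 0.29), Top2a (-2.20 ± 0.30), Rrm2 (-1.91 ± 0.38) and Pcna (-1.60 ± 0.41). Of 16 genes of intermediate progenitors and newborn neurons, 9 fell (11 adjusted over the list alone), including Neurog2 (-2.33 ± 0.26), Eomes (-1.98 ± 0.27), Neurod1 (-1.62 ± 0.30), the Notch ligand Dll1 (-2.36 ± 0.35) and Btg2 (-2.56 ± 0.41). Of 21 radial glia genes, 4 fell, with Vim at -2.89 ± 0.32 and Prom1 at -2.63 ± 0.36, and 1 rose. Of 16 Notch genes, 4 fell and 1 rose, with Hey1 at -3.53 ± 0.33 and Notch1 at -2.0 ± 0.48. Of 13 early temporal progenitor genes, the RNA-binding proteins Igf2bp1 (-1.78 ± 0.35) and Igf2bp2 (-1.59 ± 0.28) fell. Adjusted over the list alone, 8 fell and 2 rose among radial glia genes, 6 and 1 among Notch genes and 5 and 0 among early progenitor genes.

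The 5 lists passed camera (adjusted p = 5.43e-19, 1.59e-07, 0.00133, 0.000406 and 0.00227) and none did with an estimated correlation (adjusted p = 0.433, 0.377, 0.662, 0.377 and 0.377). The cell cycle median was -1.69 in IPN and -2.82 in non-IPN. The E13.5 non-IPN library, which held the hemoglobin reads and the highest radial glia sum, bore on the radial glia result: without it the list no longer passed (adjusted p = 0.388).

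Most upper-layer genes and part of the synaptic, receptor, guidance and pan-neuronal genes rose. Of 15 upper-layer genes, 11 rose and Lhx2 fell (-1.69 ± 0.40; 13 and 1 adjusted over the list alone), with Unc5d at 2.31 ± 0.49 and Limch1 at 1.82 ± 0.33. Of 20 synaptic genes, 8 rose (12 adjusted over the list alone), including Snap25 (1.85 ± 0.26), Nrxn3 (2.14 ± 0.37) and Pclo (1.21 ± 0.31). Of 17 glutamate receptor genes, 7 rose, with Gria2 at 1.45 ± 0.28 and Grik3 at 2.05 ± 0.37, and of 16 GABA receptor genes 5 rose, with Gabrb2 at 3.24 ± 0.37 and Gabbr1 at 1.51 ± 0.32. Of 24 guidance genes, 10 rose, with Robo1 at 3.18 ± 0.28, Nrp1 at 2.03 ± 0.29, Chl1 at 2.14 ± 0.23 and Cntn2 at 2.20 ± 0.39. Of 20 pan-neuronal genes, 7 rose, with Dcx at 1.69 ± 0.31 and Mapt at 1.56 ± 0.32. Adjusted over the list alone, 8 rose and 1 fell among glutamate receptors, and 6, 12 and 14 rose in the last 3 lists.

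These 6 lists passed camera (adjusted p = 7.89e-07, 3.45e-07, 0.000121, 0.000611, 5.08e-05 and 2.91e-05) and none did with an estimated correlation (adjusted p = 0.377, 0.377, 0.377, 0.592, 0.440 and 0.592). Without the E13.5 non-IPN library the glutamate receptor list no longer passed (adjusted p = 0.120), and without the E16.5 non-IPN library the pan-neuronal list did not (adjusted p = 0.0639).

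Of 18 projection neuron genes, 4 rose and 1 fell (8 and 1 adjusted over the list alone), with Mef2c at 2.79 ± 0.25, Zfp238 at 1.53 ± 0.35 and Emx2 at -2.21 ± 0.48; the list passed camera (adjusted p = 0.0142; adjusted p = 0.645 with an estimated correlation) but not without the E13.5 IPN library (adjusted p = 0.0629), the E13.5 non-IPN library (0.358) or the E16.5 non-IPN library (0.761). Of 15 Cajal-Retzius genes, 5 fell, with Nhlh2 at -3.37 ± 0.54 and Ebf3 at -1.77 ± 0.38, and A930038C07Rik (Ndnf) rose (6.77 ± 0.96); adjusted over the list alone, 11 fell and 1 rose (camera adjusted p = 5.08e-05; adjusted p = 0.377 with an estimated correlation, and 0.0636 without the E13.5 IPN library). The red blood cell list (camera adjusted p = 0.0142; 0 of 11 called) and the microglia list (adjusted p = 0.0283; 1 of 12 fell) also passed, and with an estimated correlation they did not (adjusted p = 0.713 and 0.592). Adjusted over the list alone, 1 red blood cell gene and 3 microglia genes fell. The microglia list no longer passed without the IPN or non-IPN library of E13.5 or the non-IPN library of E16.5 (adjusted p = 0.093, 0.102 and 0.394), and the red blood cell list not without the non-IPN library of E13.5 or of E16.5 (adjusted p = 0.624, with a median of 0.467, and 0.507). Genes on the interneuron lists that rose included Gad2 (1.30 ± 0.30), Dlx1 (2.07 ± 0.40) and Lhx6 (4.06 ± 0.49). Zeb2 (2.10 ± 0.27), Adarb2 (4.93 ± 0.93) and Met (3.58 ± 0.83) also rose, and Nr2f1 fell (-1.84 ± 0.27). Of these, Zeb2 and Nr2f1 were not called between the populations (0.053 ± 0.217 and -0.025 ± 0.222, limma adjusted p = 0.939 and 0.979). The lists of these genes did not pass camera, but the medial ganglionic eminence list did without the E13.5 IPN library. In the GABA and Dlx list 2 rose and 0 fell, in the medial list 3 and 0, in the caudal list 1 and 2, in the migration list 3 and 0 and in the peptide list 1 and 1 (3 and 0, 5 and 1, 1 and 2, 3 and 1, and 2 and 3 adjusted over the list alone). Ldb2, on the deep-layer list, rose (4.09 ± 0.77), Gja1 fell (-3.40 ± 0.49), and Dcn rose from a low level, 0 in IPN at E13.5 (4.88 ± 1.12). The striatal, subplate, oligodendrocyte precursor, astrocyte, endothelial, meningeal, choroid plexus, immediate early and sex-linked lists did not pass, and neither did the deep-layer list. Their called genes were 2 striatal genes and 1 astrocyte and 1 immediate early gene that fell, and 1 deep-layer and 1 meningeal gene that rose. Adjusted over the list alone, 2 striatal genes rose and 3 fell, 1 astrocyte gene rose and 1 fell, 1 immediate early gene fell, and 1 gene each of the deep-layer, meningeal and sex-linked lists rose. The deep-layer and sex-linked lists passed as higher without the E16.5 IPN library (adjusted p = 0.0245 and 0.0381), and the striatal list as lower without the E15.5 pair or with column totals (adjusted p = 0.0495 for each).

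By the rule, the largest increases included Arhgap29 (7.45 ± 1.03), A930038C07Rik, Nav2 (6.08 ± 0.55), Ptprt (5.90 ± 0.74), Lrrtm3 (5.78 ± 0.80), Nrip1 (5.37 ± 0.61) and Ccbe1 (5.28 ± 0.53). A930038C07Rik and Ptprt were listed at 0 in IPN at E13.5. At that age Arhgap29 was at 0.06 CPM in IPN and 0.21 in non-IPN, and Lrrtm3 was at 0.07 in non-IPN. The sizes of changes from such levels depend on the pseudocount. The largest decreases were the LIM homeobox factor Lhx9 (-6.70 ± 0.67), the mitochondrial iron carrier Slc25a37 (-6.39 ± 1.0), Cckar (-6.37 ± 0.83), Magel2 (-5.19 ± 0.81), Psrc1 (-4.56 ± 0.54), Dach1 (-4.13 ± 0.40) and the mitotic genes Ttk (-4.12 ± 0.71) and Kif23 (-4.03 ± 0.64). Limma called 1178 genes (6.02%), 736 higher and 442 lower at E16.5, and 15 of 30 lists passed camera, 7 higher and 8 lower, while 0 passed with an estimated correlation and 1, the list of intermediate progenitors and newborn neurons, passed fry (adjusted p = 0.0263). Without the E15.5 pair 97 genes were called, and without any single library of E13.5 or E16.5 limma called 0, with 1809 to 4025 genes at an unadjusted p under 0.05. Longer transcripts had higher E16.5 to E13.5 ratios across genes (Spearman rho 0.35 in IPN and 0.31 in non-IPN; genes are not independent replicates), and correction for length changed the split of calls from 775 higher and 516 lower to 450 and 426. Among genes with 10 CPM and a transcript length, the Cajal-Retzius and microglia lists did not pass (adjusted p = 0.224 with 6 of 15 members and 0.123 with 10 of 12), and after correction the red blood cell list did not either (adjusted p = 0.0636 with 6 of 11).

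**Figure D3:**
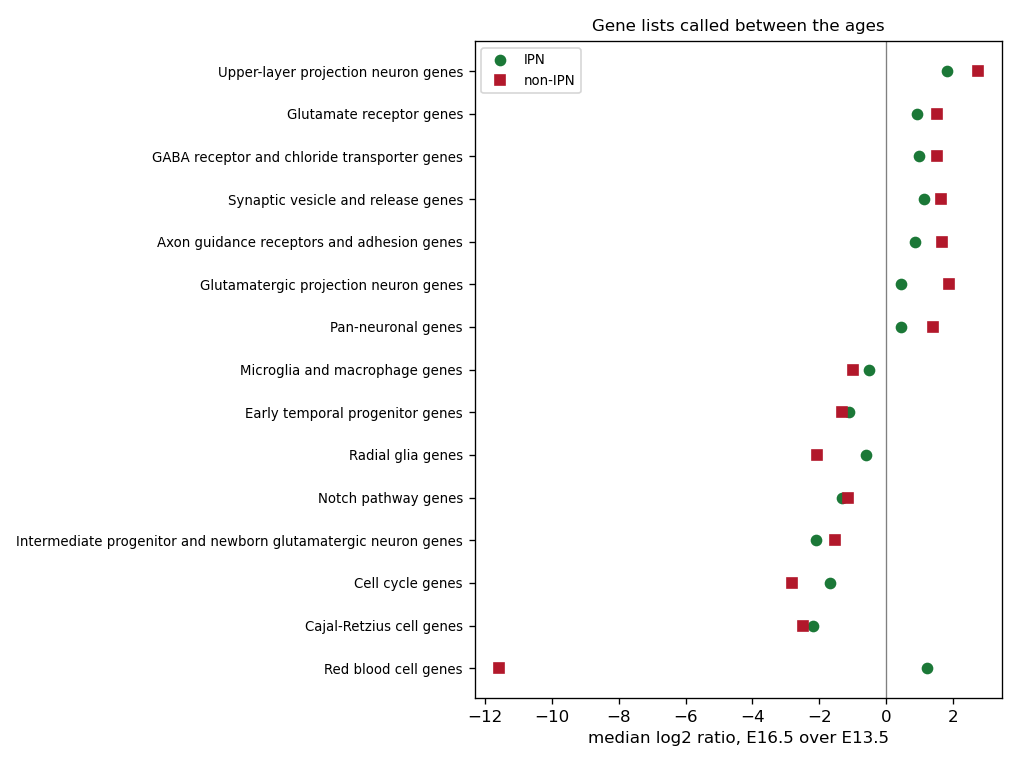
Median log2 ratio of E16.5 over E13.5 for the 15 gene lists that passed camera, with 1 point per population (green circles IPN, red squares non-IPN). The cell cycle list lies at -1.69 in IPN and -2.82 in non-IPN, and the red blood cell list lies at 1.22 and -11.60.

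The population difference was also tested for a trend with embryonic day. Of 21 radial glia genes 5, and of 29 cell cycle genes 2, were called with a rising IPN to non-IPN ratio (10 and 4 adjusted over the list alone, with 1 radial glia gene falling). Of 18 projection neuron genes, 3 were called with a falling one (3 falling and 1 rising adjusted over the list alone). These lists passed camera (adjusted p = 1.04e-05, 1.04e-05 and 0.0279) and not with an estimated correlation (adjusted p = 0.863 for each). At E13.5 the non-IPN library also held the hemoglobin and radial glia maxima given above. Limma called 255 genes with 1 residual degree of freedom, 122 with a rising and 133 with a falling IPN to non-IPN ratio. With day as a number in both terms it called 0, also after scaling to column totals or by median of ratios, with 186, 348 and 451 genes at an unadjusted p under 0.05. With another scaling and age as a factor the count was 1114 to 1559.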

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

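The tests of explanations in this part were chosen after the results were seen, except the correlation test for older projection neurons; the bound of the scaling test was also reset, from -0.5 to 0, after its value was seen, and the population by day term was planned. That term, tested as an interaction, called 255 genes whose IPN to non-IPN difference changed with embryonic day. Other splits of the libraries that part all 3 age pairs were 4 with the real one. Of the 4, 1, the real one, reached 255 and the highest of the others was 0, and 4 splits are too few for a share under 0.05. In the others the real population difference enters the residual, so their 0 does not show what chance alone would give.

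The rising genes picked by the rule were all hemoglobin genes that share reads: Hbb-b1 and Hbb-b2 (5.31 log2 units per day each), Beta-s (5.05), and Hba-a2 and Hba-a1 (4.84 each). The falling genes were Khdrbs2 (-2.25), Fcrls (-1.99), Vat1 (-1.95), Pde1c (-1.90) and Ggt7 (-1.61). At E13.5, Hbb-b1, Hbb-b2 and Beta-s were listed at 0 in IPN, with Hbb-b1 at 944.21 CPM in non-IPN, and Khdrbs2 was at 6.66 CPM in IPN and 0 in non-IPN. Fcrls was listed at 0 in IPN at E16.5, so these slopes depend on the pseudocount. The log2 ratio of Pde1c was 4.50 at E13.5 and -1.08 at E16.5.

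Among lists, 11 passed camera for this term, and 0 passed with an estimated correlation (adjusted p = 0.863) or with fry. Median slopes were 4.30 for red blood cell genes, 0.54 for radial glia genes and 0.37 for cell cycle genes. They were -0.36 for projection neuron genes, -0.28 for deep-layer genes, -0.41 for caudal ganglionic eminence genes, -0.34 for interneuron migration genes, -0.40 for pan-neuronal genes, -0.18 for synaptic genes, -0.33 for glutamate receptor genes and -0.28 for axon guidance genes.

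The falling slope of projection neuron genes goes with a smaller gap at E16.5. Scaling of the E16.5 pair would move each gene alike. The median log2 ratio of genes with 10 CPM was 0.17 at E13.5, -0.01 at E15.5 and 0.1 at E16.5. Relative to that median gene, members changed by a median of -1.47 (quartiles -1.91 and -0.43). The upper quartile of -0.43 lies above the bound first set and under the reset one, so a verdict would rest on the reset. The list values are also those that showed the smaller gap. The test therefore shows only that the list moved more than the median gene, and does not decide on scaling as the whole cause. IPN cells mixed into the E16.5 non-IPN tube would set 1 floor for all IPN genes. The test took 12 genes over 8 times higher in IPN at both earlier ages, with at least 16 CPM in IPN at E16.5. Of these, 1 (8.33%, exact binomial interval 0.211 to 38.5%), Mc4r at 0.109, lay far under the median ratio of 0.395, and 12 genes do not decide it. Among the 10 largest increases picked by the rule, E16.5 log2 ratios of IPN over non-IPN ran from 0.95 (Ryr3) to 3.19 (Mc4r). Neurod1 was at 2.67 and Nptx1 at 2.59, but each value rests on 1 library per population. Older projection neurons without GFP may also enter that gate; across the 12 genes the E16.5 ratio and the IPN age change had a Spearman rho of 0.17 (two-sided permutation p = 0.586, 100000 permutations), so mixing and older neurons cannot be told apart here.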

How the results depend on the processing

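The fits without single libraries for age, the length correction, the scalings of list counts and the fits that join 2 choices were chosen after seeing the data. Planned count models (edgeR, DESeq2, voom) and the filterByExpr filter were not run, since the values are not raw counts. The cause of each change below was not tested, except that fewer libraries or genes entered some fits. For IPN against non-IPN (664 genes), the count was 54 to 595 without single age pairs, 54 being without E15.5, 358 with a mean of 10 CPM, 362 with a transcript length and 344 corrected for length. Of the calls, 28.9% were higher in the fit reported and 43.3% with a mean of 10 CPM. With no replicate block, that is without pairing by age, limma called 0 (676 at an unadjusted p under 0.05), or 30 with column totals and 35 with median of ratios; the E15.5 files are on a higher scale. Scaling to column totals moved the median of all tested genes from -0.021 to -0.150. List counts (14) were 0 with an estimated correlation and 6 with fry, 16 with 10 CPM and a transcript length, also corrected for length, and 12 to 14 without single pairs.

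For E16.5 against E13.5 (1178 genes), the count was 697 with a pseudocount of 5, 97 without E15.5, 82 with no population term and 0 in limma without any single library of E13.5 or E16.5 (1809 to 4025 at an unadjusted p under 0.05). Among genes with 10 CPM and a transcript length, 1014 of its calls remained among 1291, and 651 among 876 after the length correction. List counts (15) were 0 with an estimated correlation and 1 with fry, 13 with 10 CPM and a transcript length, 12 corrected for length, and 10 to 17 without single libraries of those ages. The population by day count (255) was 1559 with median of ratios, 1434 with column totals, 1114 with upper quartile, 682 and 162 with pseudocounts of 0.1 and 5, 102 and 135 with the minimum levels, and 0 in limma with day as a number under each of the 3 scales tried (186, 348 and 451 at an unadjusted p under 0.05).

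Of 1209 pairs of a named gene and a setting for the populations, 888 kept direction and side of the threshold, 309 lost the call, 4 gained it and 8 reversed, all in genes not called: the Dcx population difference (0.014 with median of ratios, with or without the block, and -0.436 to 0.310 without single pairs), and likewise the Reln population (-0.885 to 0.236), Nr2f2 population (-0.722 to 0.014) and Neurog2 population (-0.309 to 0.049) differences. For age, 539 of 912 kept both and 373 lost the call, and for the day term 65 of 100 and 35, with 0 reversed. Scaled values leave the depth of a low gene unknown.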

Other observations

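The tests in this part were chosen after the results were seen, except the listing of libraries per age; 17 further microglia genes and their bound were fixed before their own values were seen. That bound replaced a first criterion, and the outcome was foreseeable, since other macrophage genes outside the lists had been seen low in IPN. The summed level of projection neuron genes was 7353.4, 10174.7 and 13486.5 CPM in IPN and 1720.4, 1606.5 and 6714.5 in non-IPN at E13.5, E15.5 and E16.5. That of GABA and Dlx genes was 116.3, 99.5 and 97.3 CPM in IPN and 1669.0, 4761.6 and 2858.6 in non-IPN.

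Microglia and macrophage genes were far higher in non-IPN, although the gate asked for DCX-driven red fluorescence. The 17 further genes, on none of the lists, had a median fitted difference of -5.17 (quartiles -6.96 and -4.22; 11 called lower in IPN, 0 higher), which is consistent with microglia among the sorted cells. The most abundant members of the microglia list itself, P2ry12 and Csf1r, were at 210.10 and 118.35 CPM in non-IPN at E13.5, 92.63 and 238.36 at E15.5 and 136.14 and 71.68 at E16.5, against at most 0.25 and 0.84 in IPN, and no member of it stands on another list. Carry-over of all non-neuronal types alike is argued against. The endothelial and pericyte list had a median of -0.40 (quartiles -1.26 and 0.39), while the microglia members ran from -5.58 to -8.87. Red blood cell genes summed to 50228.7 CPM in non-IPN and 6.2 in IPN at E13.5, sums that may hold shared reads more than 1 time. Their median log2 ratios were -12.76, -1.38 and 0.74 by age, so blood cells in the E13.5 non-IPN tube stay open. For the microglia difference, the choice among the scalings tried is argued against too, since it moved the median of genes with 10 CPM by at most 0.138. Each scaling brings the libraries to a common level, so a large move was not likely and this test adds little. Whether cells with red fluorescence transcribe the microglia genes themselves was not tested.

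The age difference came with a trend in transcript length. The median E16.5 to E13.5 log2 ratio ran from -0.46 in the shortest sixth of transcripts to 0.53 in the longest in IPN, and from -0.45 to 0.66 in non-IPN. Length bias as the whole cause is argued against: 719 of 1291 calls (55.7%) remained in the same direction after correction, and the median size of those 1291 changes went from 1.67 to 1.43. The cell cycle median went from -2.25 to -2.50, the upper-layer median from 2.23 to 1.54 and the synaptic median from 1.24 to 1.09. A difference between libraries or litters may still account for any of it, since each age had 1 library per population, and age and library cannot be told apart.

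Across the 10 splits of the 6 libraries into 3 and 3, the real split called 664 genes and the highest of the others 0, and it called 14 lists against 12. In each case 1 split, the real one, was as large, and 10 splits are too few for a share under 0.05. The other splits that part all 3 age pairs called 4 to 9 lists, and 6 splits part 1 age pair only. The term of those 6 rests on that pair, and they repeat the same fits, with 459, 1777 and 3311 genes at an unadjusted p under 0.05 against 2665 in the real split. In every other split the real population difference enters the residual, so their 0 calls do not show what chance alone would give.

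Pairs of libraries differed in how far they shared the population difference. Across 9349 genes with 10 CPM, which are not independent replicates, Pearson r of the log2 population ratios was 0.723 between E15.5 and E16.5, 0.593 between E13.5 and E15.5 and 0.471 between E13.5 and E16.5, the pair made by the same amplification. Spearman rho for the same genes was lower, at 0.435, 0.326 and 0.209 in that order.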
